A study of Homo sapiens with 21 samples.

How the data were processed

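RNA of 21 samples was measured on Illumina HumanRef-8 v3 bead arrays. Per the labels, total RNA that included small RNA was extracted with a miRNeasy kit, passed a lower limit on RNA integrity and was made into biotinylated cRNA with the Ambion MessageAmp kit. The labels name 3 preparations of CD34+ cells (A to C), each at D0 and D21, read here as days of culture in StemPro medium with supplement. They also name basophils, eosinophils and pDC of 5 donors (A to E), with the 3 cell types of a donor from the same blood draw. The letters of the CD34 preparations and of the blood donors belong to separate experiments.

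The deposited values were probe intensities on a linear scale. The scanner software, background handling and normalization by the authors are not stated. From the values themselves, no array had intensities below 1, and the lowest of all was 34. This shows no background subtraction down to 0, but one followed by an added offset cannot be told from the values. The quantiles differed between arrays, so there was no quantile normalization. The columns of CD34 preparations A and B carried fewer decimals than those of preparation C and donor A. This was balanced over the days of the culture, but not between donor A and day 21. No counts lie behind bead array intensities here, and precision rests on the number of arrays.

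The table held 24526 probes. Of these, 21834 carried 1 gene symbol, 2692 carried none and 0 carried several, which gave 16864 genes. No symbol was changed, and 21813 probes had a current gene identifier. For the 3188 genes with more than 1 probe, the probe with the highest mean over the 9 arrays was used, and 0 genes had probes called in both directions. The 67 probes of the Y chromosome and XIST were left out of named results, gene names starting LOC, immunoglobulin and T cell receptor segments and HLA-DRB and HLA-DQ genes were not named, and no genome coordinates were used.

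Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The planned test was 1 fit of all 21 arrays. The values of 12 arrays (donors B to E) did not follow the probe rows, as the correlations between arrays in the results show, so this plan was changed after the values were seen. Named genes were tested in the 9 arrays of the CD34 culture and donor A, and the fit of all 21 arrays became an alternative. Donors B to E were compared with one another on all 24526 rows without names, with 4 arrays per cell type.

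Values were quantile normalised between arrays and taken to log2, separately for the 9 and the 12 arrays. Groups were compared in R 4.3.3 with limma 3.58.1 and statmod 1.5.0 (lmFit and eBayes, a mean per group, blocks as fixed factors). A Benjamini-Hochberg adjusted p under 0.05 over all genes or rows was the threshold. In the fit of 9 arrays, the 3 single blood arrays gave no spread of their own, so their tests against day 21 assumed the spread of the CD34 arrays, with 4 residual and 2.09 prior degrees of freedom. The same test between pairs of single blood arrays was left out by choice. These pairs are described by their largest differences, by list members at least 4-fold apart and by the rank of each list median among 10000 random lists matched on expression, all of which were chosen after the values were seen.

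The 29 gene lists held 431 distinct genes, of which 399 were measured. Each list was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. With an estimated correlation, camera also limits the degrees of freedom of its test to the 4 residual ones. The estimate lay below 0.01 for some lists, such as mast cell genes (−0.0720) and ribosome biogenesis (−0.0454). A call lost in this setting therefore need not reflect correlated genes. A fry p tests whether the genes of a list move one way on balance, and its mixed p whether they change in either direction. Fry passed for 17 lists in the CD34 comparison and 9 in the basophil comparison, and its mixed p for 27 and 19. The named genes were the 10 highest and 10 lowest among called genes without overlap between groups, up to 4 called members of each list, and CD34, LYN and SYK whatever their values. Where 5 or fewer members of a list passed, those outside this rule were also named, after their values were seen, as were the day 21 levels by preparation. Other genes on the lists or in the rule were not analysed here. The sets of 100 blood lineage genes were taken from the single arrays of donor A, by the smaller of the differences to the other blood cell types, in place of a replicated fit of 15 arrays. Correlations between profiles were tested with exact permutation or sign-flip tests.

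The pairing of samples rests on the labels. The deviations of preparations A, B and C from their group means at day 0 and day 21 correlated across genes at r = 0.142, 0.0948 and 0.410, and those of donors across cell types at 0.0393 to 0.363. The preparation or donor as a block was an alternative, which gave 837 genes higher and 1006 lower in the CD34 comparison. Of the 91 genes named there by rule, 7 lost their call with the block.

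The tests were tried on simulated data, with 100 genes changed by 1 and 100 by 2 on the log2 scale in arrays of the same number and spread. The CD34 comparison recovered 45% and 81%, with 4.55% false among its calls. The comparison of the single basophil array with day 21 recovered 8% and 59%, with 0% false. Its simulated basophil array was given the spread of the CD34 arrays, which is what the test itself assumes. The share of false calls for the real basophil array therefore stays unknown. The row comparisons of donors B to E recovered 91% to 95% and 98% to 100%, with 5.45% to 5.88% false. The alternatives were cyclic loess, median centring, the values as deposited, dim genes left out, the mean of probes, fits of the compared groups only, the trend and robust options, array weights, a 2-fold minimum, an adjusted p under 0.01, the block, each array left out in turn, and 50 or 200 lineage genes. Added after the values were seen were the fit of all 21 arrays, a normexp background step with an offset of 50, and the CD34 comparison without preparation B on both days.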

Results

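Gene expression was measured on 21 Illumina bead arrays, 1 per sample. Of these, 6 arrays came from CD34+ blood progenitor cells grown in StemPro medium, with 3 preparations (A to C) sampled at day 0 and again at day 21. The other 15 arrays came from basophils, eosinophils and plasmacytoid dendritic cells (pDC), the blood dendritic cells specialised in type I interferon secretion. Each of these cell types was purified from the same blood draw of 5 donors (A to E), to an average of 99% per the labels. No cells were treated. The mean intensity per array was 413 to 597 at day 0, 447 to 1042 at day 21, 440 to 976 in basophils, 377 to 797 in eosinophils and 424 to 939 in pDC. The share of probes brighter than 2 times the array's 25th percentile was 38.8% ± 4.17 (SD, n = 3) at day 0 and 40.3% ± 5.88 (SD, n = 3) at day 21. It was 39.2% ± 2.80 in basophils, 37.4% ± 2.39 in eosinophils and 41.5% ± 2.80 in pDC (SD, n = 5 each). The number of arrays limits the precision of every value.

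Probes for several abundant transcripts gave bright signals in donor A and much weaker ones in donors B to E. A probe for beta-actin (ACTB, ILMN_2038777) read 21611 in the basophil array of donor A, but 624 to 1099 in the basophil arrays of donors B to E. A probe for histidine decarboxylase (HDC), the enzyme that makes histamine, read 24680 in the basophils of donor A and 107 to 167 in those of the other donors. The probe for CLC, which encodes the Charcot-Leyden crystal protein of eosinophils and basophils, was bright in both, at 27134 in the basophils of donor A and 11808 to 13960 in those of the others. In pDC, however, it read 69 in donor A and 2564 to 3285 in the others. Across all 24526 probes, the 6 CD34 arrays and the 3 arrays of donor A correlated with one another at r = 0.801 to 0.967. The arrays of donors B to E correlated at r = 0.985 to 0.994 within a cell type and at 0.835 to 0.929 between cell types. Between these sets of 9 and 12 arrays, r was 0.0774 to 0.107. These correlations run across probes, which are not independent replicates. The values of donors B to E therefore were not read by probe name, and the named genes in the comparisons that follow come from the 9 other arrays. The 12 arrays were compared with one another on rows without names.

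**Figure D1:**
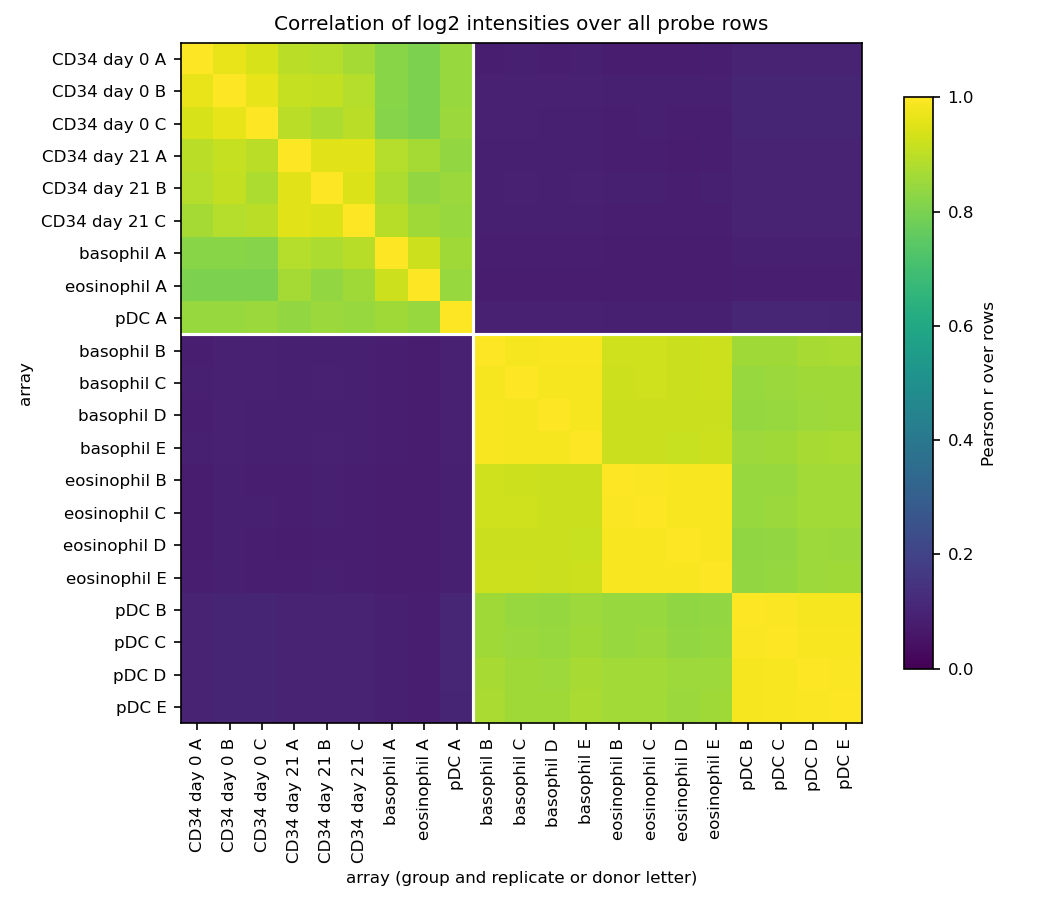
Pearson correlation of log2 intensities over all 24526 probe rows for every pair of the 21 arrays, on a colour scale from 0 to 1, with white lines between the 9 arrays of the culture and donor A and the 12 arrays of donors B to E. Correlations between these sets lie between 0.0774 and 0.107, against at least 0.801 within the 9 arrays and at least 0.835 within the 12.

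The first comparison asks how the CD34+ cells differed between day 0 and day 21. CD34 itself, the surface marker by which progenitors are selected, fell by 6.11 on the log2 scale, from 12.83 ± 0.42 to 6.71 ± 0.71 (SD, n = 3 each, adjusted p = 0.00102). HDC rose by 4.28, from 10.45 ± 0.78 to 14.72 ± 0.23 (SD, n = 3 each, adjusted p = 0.00324). CLC rose by 7.41 to 15.31 ± 0.08 (SD, n = 3, adjusted p = 0.000676).

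The 10 genes with the largest rises included TCN1, a vitamin B12 binding protein of granulocyte granules, at 7.52 (adjusted p = 0.000515). GPNMB, a glycoprotein abundant in macrophages, rose by 6.91, and the granule proteins RNASE2 and PRG2 by 6.40 and 6.31. CFD, the complement protease factor D, rose by 6.10, RNASE1 by 6.08 and the formyl peptide receptor FPR1 by 5.55. ALOX5AP and ALOX5, which start leukotriene synthesis, rose by 5.96 and 5.49. Besides CD34, the 10 genes with the largest falls were ADGRG1 at −5.22, DPYSL3 at −4.91, DNTT, the template-independent DNA polymerase of early lymphoid cells, at −4.83, and the histone gene H2BC8 at −4.80. SPINK2 and PROM1, both progenitor markers, followed at −4.54 and −4.47, and MYO5C, GBP4 and ABLIM1 at −4.40, −4.33 and −4.04. Probes at or under 2 times the 25th percentile, 6.88 on this scale, were taken as dim, a limit chosen after the values were seen. TCN1, GPNMB, RNASE1 and FPR1 were dim at day 0, and 8 of the 10 falling genes, without SPINK2 and PROM1, were dim at day 21. These differences are lower bounds, and so is that of CLC, whose day 21 level lay near the top of the scale (15.40). Their order is not exact. A lower bound, or "at least" or "or more" with a log2 difference, means that an end of the scale can shrink that difference. It does not cover the spread between arrays, which can move a mean either way. The plot of the genes with the largest changes shows each of the genes named above per array.

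Of 13 measured genes of basophil identity, 10 rose over all genes tested and 13 adjusted over the list alone, with a list median of 3.61. ENPP3, the basophil surface marker CD203c, rose by at least 4.51, MS4A3 by 4.43, HDC by 4.28 and AKAP12 by 4.11. The list stood above the other genes with camera (adjusted p = 1.32e-13), and its call held with an estimated correlation (adjusted p = 0.0228). In the IgE receptor signalling list, 5 of 24 genes rose and 1 fell (7 and 2 adjusted over the list alone). FCER1G, the signalling gamma chain of the receptor, rose by 4.97, the adaptors LAT and GAB2 by 3.15 and 1.69, the calcium channel ORAI1 by 1.43 and PLCG2 by 1.12. LYN, the kinase that phosphorylates the receptor, fell by 0.92 (adjusted p = 0.0455), and SYK, the kinase recruited next, differed by 0.41 (adjusted p = 0.423). This list passed with camera (adjusted p = 0.00556), but adjusted p = 0.318 with an estimated correlation.

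Of 5 eosinophil granule proteins, 3 rose (CLC, RNASE2 and PRG2), and 5 did so adjusted over the list alone. The list median was 6.31 and camera gave an adjusted p = 4.57e-06, with adjusted p = 0.0964 with an estimated correlation. Between the single basophil and eosinophil arrays of donor A, 0 of these 5 genes differed at least 4-fold in either direction (median −0.17). In eosinophil identity, CLC alone of 11 genes rose over all genes tested, and 5 rose adjusted over the list alone (camera adjusted p = 0.000105, adjusted p = 0.0874 with an estimated correlation). Mast cell genes had 5 of 9 higher, also 5 adjusted over the list alone. These were CTSG (3.95), SIGLEC6 (3.82), the carboxypeptidase CPA3 (3.81), HPGD (2.78) and MITF (0.83). CPA3 is also on the basophil identity list and CTSG on that of neutrophil granule proteins. The blood lineage genes taken from the basophil array of donor A held 4 mast cell genes. Of these, CPA3, CTSG and HPGD rose. The rise of the mast cell list therefore cannot be assigned to mast cells rather than basophils. The list's camera adjusted p was 4.82e-05, with adjusted p = 0.0523 with an estimated correlation.

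Of 12 neutrophil granule proteins, 5 rose (7 adjusted over the list alone). These were the elastase ELANE at 4.79, lysozyme LYZ at 3.97, the protease CTSG at 3.95, AZU1 at 3.10 and CEACAM8 at 1.60. Camera gave an adjusted p = 0.000105, with adjusted p = 0.0912 with an estimated correlation. Of 12 monocyte and macrophage markers, 5 rose (5 adjusted over the list alone). These were the scavenger receptor CD163 at 5.24 or more, the lipopolysaccharide co-receptor CD14 at 4.45, LYZ at 3.97, MS4A6A at 3.83 or more and CSF1R, the receptor for macrophage colony-stimulating factor, at 3.80 or more. The list median was 2.42 and camera gave an adjusted p = 1.35e-05, with adjusted p = 0.274 with an estimated correlation. The day 21 levels differed between preparations, with CD163 at 9.01 in A, 12.73 in B and 11.47 in C, and GPNMB at 11.01, 14.26 and 12.88. CD163, CD14, MS4A6A and CSF1R lost their calls without any 1 of the day 0 arrays or the day 21 array of C, and the last 2 also without the day 21 array of B. Their adjusted p then reached 0.0725, 0.0773, 0.130 and 0.140. Mature neutrophil markers had 0 of 10 past the limma threshold in either direction, and 0 adjusted over the list alone. At an unadjusted p under 0.05, 2 of these were higher (camera adjusted p = 0.563, fry 0.371).

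Of 23 cytokine receptors, 9 rose and 0 fell (14 and 1 adjusted over the list alone), with a median of 1.46. IL18R1 rose by at least 4.87, CSF2RB, the shared signalling chain for IL-3, IL-5 and GM-CSF, by at least 4.07, CSF1R by at least 3.80 and the IL-33 receptor IL1RL1 by at least 3.48. Of 20 chemoattractant, lipid and amine receptors, 9 rose and 0 fell (12 and 0 adjusted over the list alone), with FPR1 at 5.55, C3AR1 at 3.73, the prostaglandin D2 receptor PTGDR2 at 3.61 and CXCR4 at 3.48. Camera gave adjusted p = 5.26e-08 and 3.93e-08 for these lists, and both calls held with an estimated correlation (adjusted p = 0.0228 each). In eicosanoid synthesis, 4 of 13 genes rose and 1 fell (4 and 2 adjusted over the list alone), namely ALOX5AP, ALOX5, the leukotriene C4 synthase LTC4S at 5.18 and the prostaglandin D synthase HPGDS at 2.21, against ALOX12, which was dim on both days. Its camera adjusted p was 0.0229, with adjusted p = 0.274 with an estimated correlation. Without the day 21 array of preparation A it was 0.0514, and without that of preparation C 0.0529.

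The haematopoietic stem and progenitor list fell, with 9 of 16 genes lower and 0 higher (11 and 0 adjusted over the list alone) and a median of −2.34. The fall was led by CD34, SPINK2, PROM1 and MECOM, a stem cell transcription factor, at −3.32 (camera adjusted p = 2.00e-10, and adjusted p = 0.0443 with an estimated correlation). Ribosome biogenesis also fell, with 9 of 18 genes lower (14 adjusted over the list alone) and a median of −1.16. RRP12 stood at −2.26, the nucleolar methyltransferase FBL at −1.96, and NOP58 and the RNA polymerase subunit POLR1C at −1.68 each (camera adjusted p = 6.51e-10, and adjusted p = 0.0228 with an estimated correlation). In the cell cycle list, 10 of 25 genes rose and 0 fell (12 and 0 adjusted over the list alone), with topoisomerase TOP2A at 2.50, CDK1 at 2.05 and the mitotic kinases AURKB and AURKA at 1.79 and 1.70. Its camera adjusted p was 2.76e-05, with adjusted p = 0.392 with an estimated correlation and 0.0572 with fry.

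Of 14 type I interferon response genes, 4 fell (6 adjusted over the list alone). These were the antiviral GTPase MX1 (−3.58), XAF1 (−2.63), OAS2 (−2.39) and IFI44L (−2.17) (camera adjusted p = 0.000122, adjusted p = 0.213 with an estimated correlation). Of 15 immediate early and heat shock genes, 3 fell (4 adjusted over the list alone), namely HSPA1B (−2.87), JUN (−2.84) and ATF3 (−2.64). Camera gave an adjusted p = 0.0335, with adjusted p = 0.503 with an estimated correlation and 0.182 with fry. Without the day 21 array of preparation A it was 0.429, and without the day 0 array of preparation C 0.0713. In the Toll-like receptor pathway, 3 of 14 genes rose (3 adjusted over the list alone), namely TLR4 by 2.54, UNC93B1 by 2.35 and the adaptor MYD88 by 1.59. Its camera adjusted p was 0.0149, with adjusted p = 0.373 with an estimated correlation, and 0.0580 without the day 0 array of preparation C. In apoptosis and survival, 3 of 16 genes rose (3 adjusted over the list alone), namely the survival genes BCL2 by 3.24, BCL2A1 by 1.65 and CFLAR by 1.35 (camera adjusted p = 0.00387, adjusted p = 0.0918 with an estimated correlation).

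Haematopoietic transcription factors moved in both directions, with 5 of 27 higher and 5 lower (7 and 7 adjusted over the list alone, camera adjusted p = 0.741). CEBPA and CEBPB, regulators of myeloid genes, rose by 2.77 and 2.38, RUNX1 by 1.81, SPI1 by 1.37 and MITF by 0.83. The inhibitors of DNA binding ID3 (−3.09) and ID1 (−2.40) fell, as did LMO2 (−1.94), TCF4 (−1.80) and MYC (−1.42). Of 24 pDC identity genes, MZB1 (−3.04), BCL11A (−2.24) and TCF4 fell and 0 rose (3 and 1 adjusted over the list alone). The median of that list was 0.01, its mean −0.03 and its camera adjusted p = 0.916. In MHC class II presentation, 2 of 11 genes rose (3 adjusted over the list alone), the lysosomal enzymes LGMN at 4.21 and IFI30 at 4.10. The median was −0.10, the mean 0.73 and the camera direction upwards (adjusted p = 0.241, and 0.000268 without the day 21 array of preparation A). In endoplasmic reticulum secretory machinery, SPCS1 rose by 0.83 and the chaperones HSPA5 (−1.69) and HSP90B1 (−1.21) fell, among 17 genes (1 and 2 adjusted over the list alone, camera adjusted p = 0.916, upwards with a mean of −0.11). In oxidative phosphorylation, the complex I subunits NDUFS3 (−1.45) and NDUFV1 (−0.83) fell among 17 genes (2 adjusted over the list alone, camera adjusted p = 0.118, and 0.0409 without the day 21 array of preparation C).

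Of 9 NK cell markers, NKG7 rose by 2.08 and GNLY by 1.04 (3 adjusted over the list alone, camera adjusted p = 0.128, and 0.0481 without the day 21 array of preparation C). CD79A fell by 1.50 among 8 B cell markers (1 adjusted over the list alone, adjusted p = 0.105, and 0.0256 without the day 0 array of preparation B). Carbonic anhydrase CA1 fell by 1.50 among 13 erythroid genes (1 lower and 1 higher adjusted over the list alone, adjusted p = 0.583). GNG11 fell by 3.34 among 10 platelet and megakaryocyte genes (1 adjusted over the list alone, adjusted p = 0.452). CLEC9A fell by 1.63 among 12 conventional dendritic cell markers (1 adjusted over the list alone, adjusted p = 0.563, with a median of 0.12, a mean of −0.14 and the camera direction upwards). T cell markers had 0 of 10 past the limma threshold, and 0 adjusted over the list alone. At an unadjusted p under 0.05, 1 of these was higher (camera adjusted p = 0.824, fry 0.866).

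**Figure D2:**
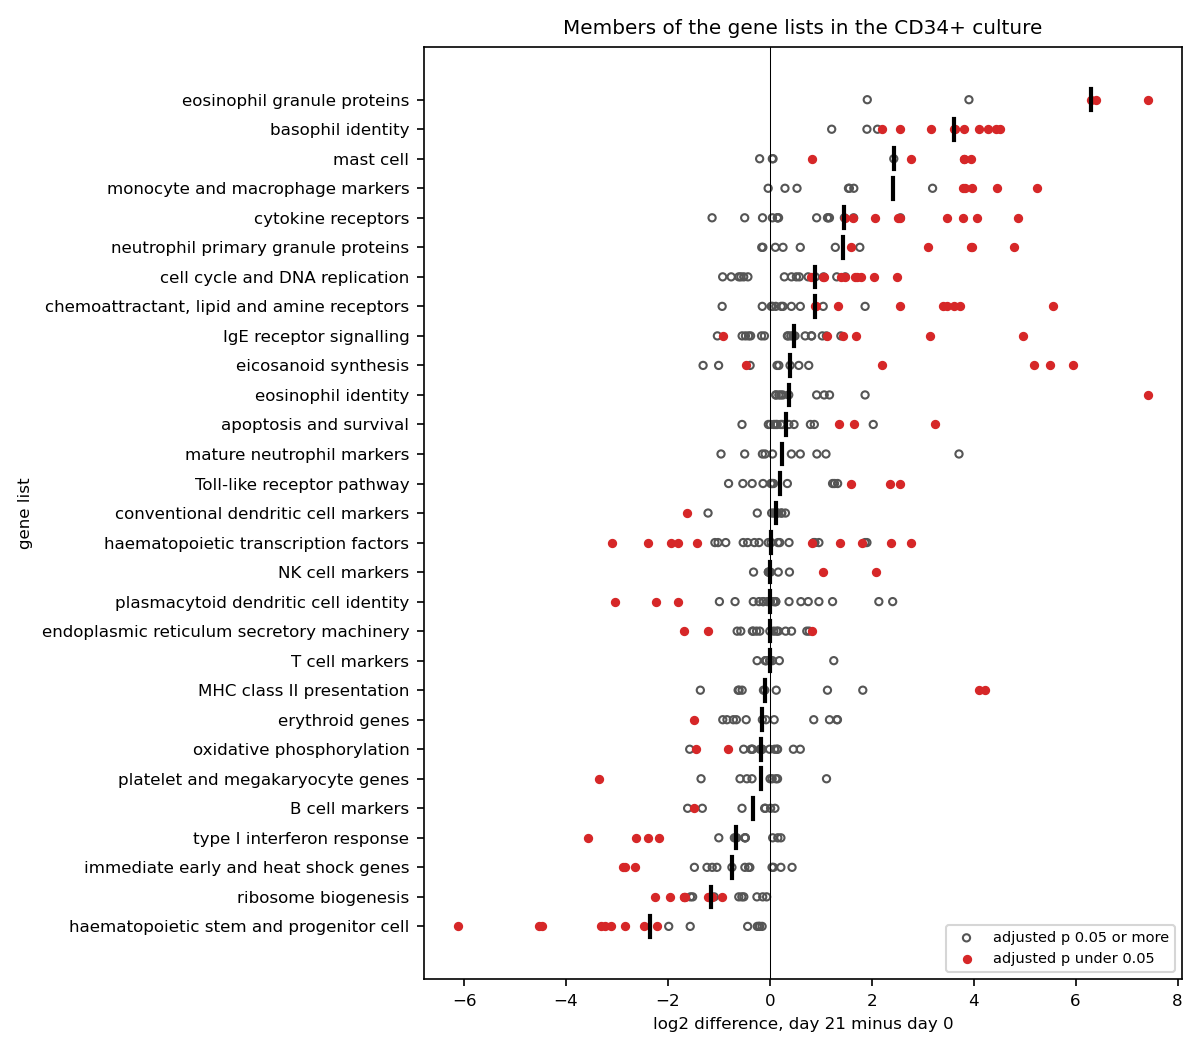
Log2 difference between day 21 and day 0 of the CD34+ culture for each measured member of the 29 gene lists, with filled points for genes at adjusted p under 0.05 and a black bar at each list median. Eosinophil granule proteins (median 6.31) and basophil identity (3.61) lie highest, and the stem and progenitor list (−2.34) lies lowest. The plot labels the neutrophil granule list as primary, though it is not limited to primary granules.

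Over all 16864 genes, 756 rose and 861 fell with limma (9.59%), of which 622 and 608 changed at least 2-fold. The 1617 called genes showed no overlap between the days, and neither did 28.0% of all genes, against 10% by chance. Of the 29 lists, 13 stood higher and 4 lower with camera's preset correlation, and 3 and 2 with an estimated one. The latter setting also used fewer degrees of freedom. Median centring of the arrays gave 550 higher and 301 lower, a share higher of 64.6% in place of 46.8%, and the values as deposited gave 154 and 76, a share of 67.0%. The count of rising genes was 368 without the day 0 array of preparation B. The count of falling genes was 480, 461 and 447 without the day 21 arrays of preparations A, B and C, and 462 without the day 0 array of B. Without preparation B on both days, 156 rose and 127 fell. None of the 20 genes with the largest changes lost its limma call when 1 of the 6 arrays was left out, but 30 of the 71 other genes named by rule did so for at least 1 array. Besides the 4 macrophage genes and LYN (adjusted p up to 0.130), these were AURKA, AURKB, BCL2A1, CD79A, CDK1, CFLAR, CTSG, GAB2, GNLY, HPGD, HPGDS, HSP90B1, HSPA1B, HSPA5, ID1, ID3, IFI44L, JUN, LGMN, MYD88, NDUFS3, NDUFV1, NKG7, RRP12 and XAF1. Leaving out the day 0 arrays of A, B and C ended 21, 22 and 21 of these calls, and leaving out the day 21 arrays ended 17, 18 and 24. Of 19 called genes named outside the rule, ALOX12, CEACAM8, CYB561A3, HES4, MITF, MYC, SGK1 and SPI1 also lost theirs (adjusted p up to 0.144). Besides the 20 genes with the largest changes, 40 of the 90 others named from this comparison were dim on at least 1 day, so their differences are lower bounds without an exact order, and medians of lists that hold them are not exact. These were AFF3, ALOX12, AZU1, C3AR1, CA1, CCNA1, CD163, CD200R1L, CD79A, CEACAM8, CLEC9A, CSF1R, CSF2RB, ENPP3, ENTPD1, GNG11, GNLY, HES4, HPGDS, ID1, ID3, IFI30, IFI44L, IL18R1, IL1RL1, LGMN, MAF, MECOM, MITF, MS4A6A, MX1, MZB1, OAS2, PTGDR2, PTGDS, RRP12, SETBP1, SIGLEC6, TLR4 and TOP2A.

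The second comparison sets the basophil array of donor A against the 3 day 21 cultures. MX1 read 14.13 in the basophils and 6.58 ± 0.20 (SD, n = 3) at day 21, a difference of 7.55 (adjusted p = 0.00169), and IFIT1 was 6.09 higher. GPNMB read 5.64 in the basophils and 12.72 ± 1.63 (SD, n = 3) at day 21, a difference of −7.08 (adjusted p = 0.0246). CD34 differed by 0.47 (adjusted p = 0.752), LYN by 0.80 (adjusted p = 0.199) and SYK by −0.91 (adjusted p = 0.223). With 1 basophil array, the limma test assumed that it varies like the CD34 arrays, and cell source, preparation and donor were not separable from culture.

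The genes brighter in the blood basophils included the neutrophil defensins DEFA1 (7.87), DEFA3 (7.15) and DEFA1B (6.45), whose nearly identical sequences the probes were not shown to tell apart. XAF1 was 5.85 and IFI44L 5.76 higher, and TRIM51, FOLR3 and ADAM19 were 5.98, 5.72 and 5.56 higher. Besides GPNMB, the 10 genes with the largest differences downwards were PRG2 at −6.29, RNASE1 at −5.93, the sterol synthesis enzyme CYP51A1 at −5.32 and the prostaglandin D synthase PTGDS at −5.30. PLPP1 followed at −5.18, ADAMDEC1 and LGALS3 at −4.86 each, TGFBR3 at −4.84 and the fatty acid desaturase SCD at −4.82. The 3 defensins, MX1, IFIT1, IFI44L and FOLR3 were dim at day 21, and GPNMB, RNASE1, CYP51A1, PTGDS, PLPP1 and ADAMDEC1 were dim in the basophils, so these differences are lower bounds without an exact order.

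Of 14 interferon response genes, 12 were higher (12 adjusted over the list alone) with a median of 3.35, and camera gave an adjusted p = 7.09e-13. With an estimated correlation the adjusted p was 0.160. Of 25 cell cycle genes, 10 were lower (15 adjusted over the list alone), led by thymidylate synthase TYMS at −4.06, CDK1 at −3.48, CCNB2 at −3.29 and PCNA at −3.25 (camera adjusted p = 7.09e-13, adjusted p = 0.327 with an estimated correlation). Of 20 chemoattractant, lipid and amine receptors, 5 were higher (8 higher and 1 lower adjusted over the list alone), namely CCR2 at 2.27, PTAFR at 1.53, LTB4R at 1.10, C3AR1 at 1.04 and FPR2 at 0.94. Camera gave an adjusted p = 0.00199, with adjusted p = 0.160 with an estimated correlation. Mature neutrophil markers had 0 of 10 past the limma threshold over all genes tested, 8 higher at an unadjusted p under 0.05 and 8 higher adjusted over the list alone. The camera adjusted p was 0.000535, fry gave 0.00902, and with an estimated correlation the adjusted p was 0.160. MYD88 at 2.19 and IRF7 at 2.01 were higher among 14 Toll-like receptor pathway genes (3 adjusted over the list alone, camera adjusted p = 0.00277, adjusted p = 0.384 with an estimated correlation).

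The IL-5 receptor chain IL5RA was 3.43 higher, the 1 called gene among the 11 of eosinophil identity (2 adjusted over the list alone, camera adjusted p = 0.0282, adjusted p = 0.327 with an estimated correlation). It was also the 1 called gene among 23 cytokine receptors (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.587). KLRB1 was higher, though dim in both, among 9 NK cell markers (4 adjusted over the list alone, camera adjusted p = 0.0407, adjusted p = 0.327 with an estimated correlation). PRG2 was the 1 called gene among 5 eosinophil granule proteins (2 lower adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.386 with an estimated correlation). FBL at −2.05, NOP58 at −1.37 and NCL at −1.04 were lower among 18 ribosome biogenesis genes (4 adjusted over the list alone, camera adjusted p = 0.0110, adjusted p = 0.217 with an estimated correlation). MHC class II presentation had 0 of 11 past the limma threshold and 0 adjusted over the list alone, with 2 lower at an unadjusted p under 0.05. Its camera adjusted p was 0.0493, with 0.477 with fry and adjusted p = 0.657 with an estimated correlation. Without the day 21 array of preparation B, camera gave 0.0513 for eosinophil identity, 0.0513 for NK cell markers and 0.188 for MHC class II, and without that of preparation C the last 2 were 0.150 and 0.144.

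The other 19 lists did not pass with camera. Of 13 basophil identity genes, the cytokine IL4 was higher at 2.79 (3 adjusted over the list alone, adjusted p = 0.247). DEFA3, DEFA4 (5.17), CAMP (3.48) and LTF, dim in both, were higher among 12 neutrophil granule proteins (6 higher and 5 lower adjusted over the list alone, adjusted p = 0.304, fry 0.000478, median −0.29, mean 0.52, camera direction upwards). FCN1, a lectin of monocytes, was 5.24 higher and CD68 differed by −1.80 among 12 monocyte and macrophage markers (2 and 2 adjusted over the list alone, adjusted p = 0.675, median −0.34, mean 0.20). IRF7, ZDHHC17 (1.41) and GZMB, dim in both, were higher among 24 pDC identity genes (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.911). SIGLEC6 was lower at −3.52 among 9 mast cell genes (1 adjusted over the list alone, adjusted p = 0.0679, fry 0.00902), and LTC4S at −4.14 among 13 eicosanoid synthesis genes (1 adjusted over the list alone, adjusted p = 0.304). UQCRC2 at −2.25 and COX7B at −1.57 were lower among 17 oxidative phosphorylation genes (2 adjusted over the list alone, adjusted p = 0.247). RUNX1 was 1.46 higher and MYC was lower at −3.32 among 27 haematopoietic transcription factors (2 and 2 adjusted over the list alone, adjusted p = 0.615). The lipid phosphatase INPP5D was 1.20 higher among 24 IgE receptor signalling genes (1 adjusted over the list alone, adjusted p = 0.528). The 9 lists not named so far in this comparison had 0 genes past the limma threshold over all genes tested and 0 adjusted over the list alone. Among these, immediate early and heat shock genes had 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0679, and 0.000146 without the day 21 array of preparation A, fry 0.437) and secretory machinery 3 higher and 2 lower (0.593, fry 0.477). Apoptosis and survival had 1 each way (0.749, fry 0.830), conventional dendritic cell markers 1 higher (0.528, fry 0.0236), and the progenitor and platelet lists 1 lower each (0.304 and 0.307, fry 0.477 each). Erythroid, B cell and T cell genes had 0 at an unadjusted p under 0.05 (0.381, 0.759 and 0.499, fry 0.708, 0.972 and 0.153).

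Over all genes, 438 were higher and 433 lower in the blood basophils with limma, 398 and 411 at least 2-fold. The eosinophil array of donor A had 809 higher and 763 lower than day 21, and the pDC array 912 and 767. Against the quantile values, median centring moved the median of all genes by 0.14, 0.13 and 0.11 for basophils, eosinophils and pDC, and the values as deposited moved it by −0.15, −0.24 and −0.19. For basophils these scalings gave 161 and 147, and 35 and 11, a share higher of 76.1% in place of 50.3% for the values as deposited. The basophil count of higher genes was 264 without the day 21 array of preparation A and 209 without that of B, and its count of lower genes was 258 without that of B. The eosinophil counts were 462 higher and 493 lower without the day 21 array of B. Of the 20 basophil genes with the largest differences, GPNMB, PLPP1, PRG2, RNASE1 and TRIM51 lost their calls without at least 1 of the 3 day 21 arrays, with adjusted p up to 0.0558, 0.0756, 0.0593, 0.0923 and 0.0609, as did 18 of the 33 other genes named by rule. Leaving out the arrays of A, B and C ended 15, 16 and 17 calls. The calls of C3AR1, CD68, COX7B, FBL, GZMB, INPP5D, LTB4R, LTC4S and ZDHHC17 (adjusted p up to 0.117), and of FPR2, named outside the rule (up to 0.0813), were lost whichever of the 3 was left out. The others lost without 1 or 2 of these were FCN1, IL4, KLRB1, LTF, MYC, MYD88, NCL, NOP58 and PTAFR. Besides the 20, 12 of the 34 other genes named here were dim in at least 1 of the groups compared, namely CCNB2, CCR2, CD34, CDK1, DEFA4, FPR2, GZMB, KLRB1, LTF, MYC, SIGLEC6 and TYMS.

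**Figure D3:**
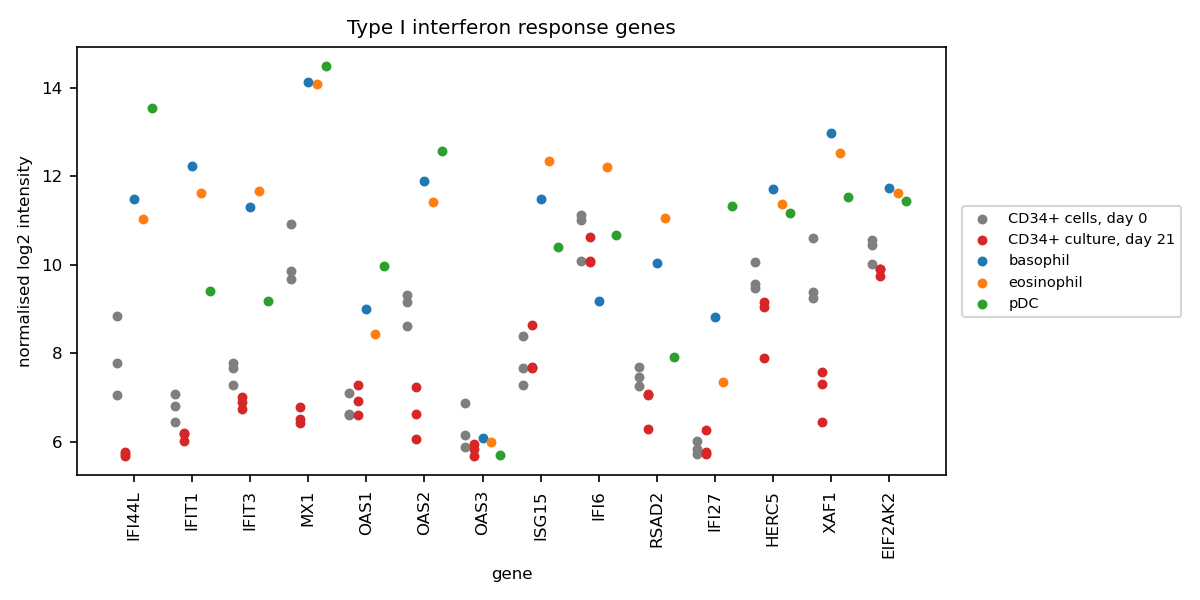
Normalised log2 intensity of the measured type I interferon response genes in the 3 day 0 arrays, the 3 day 21 arrays and the basophil, eosinophil and pDC arrays of donor A, 1 point per array. MX1 lies at 14.13 in the basophils against a mean of 6.58 at day 21.

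The third comparison asks how basophils and eosinophils from the same blood differed. In donor A, HDC read 15.26 in basophils and 7.25 in eosinophils, a difference of 8.01. GATA2, the transcription factor of basophils and mast cells, was 7.83 higher, MS4A3 7.53, CPA3 7.17 and ENPP3 6.57. TCN1 was 7.98 higher, TRIM51 7.40, DEFA1 6.52, the transporter SLC45A3 6.38 and DEFA3 6.36. Eosinophils exceeded basophils for the transcription factor OLIG2 (−6.08), the lipoxygenase ALOX15 (−5.72), the lectin SIGLEC10 (−5.68) and the serine protease PRSS33 (−5.28). They did so too for FOSB (−6.92), RGS1 (−6.87), HES4 (−6.40), CCN3 (−5.70), SGK1 (−5.30) and JUN (−5.04). There was 1 array per cell type and these differences carry no test. GATA2, CPA3, ENPP3 and DEFA3 were dim in eosinophils, and HES4, OLIG2, ALOX15, CCN3 and JUN in basophils, which makes their differences lower bounds. Those of HDC and TCN1, which lay near the top of the scale in basophils, are lower bounds as well.

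Of 13 basophil identity genes, 11 were at least 4-fold higher in basophils, with a median of 5.64, above all 10000 random lists of like expression. Of 11 eosinophil identity genes, 7 were at least 4-fold lower, with a median of −3.67, below all of them. Basophils were at least 4-fold higher for 8 of 12 neutrophil granule proteins (median 2.73), among them DEFA4 (at least 5.18) and ELANE (at least 3.98). The same held for 5 of 12 monocyte and macrophage markers, namely MS4A6A (6.15), CD14 (5.31), VCAN (at least 4.56), FCN1 (4.22) and CD163 (at least 3.52). CD14 read 13.54 in the basophil array and 8.23 in the eosinophil array. Eosinophils were at least 4-fold higher for CD3D, CD2 and CD6 among 10 T cell markers, and CD3D read 8.55 there. For such neutrophil, monocyte and T cell genes, other cells left in a sorted sample cannot be told apart from expression in the named cells. Of 24 IgE receptor signalling genes, the adaptors LAT2 (4.92), GAB2 (3.36), LAT (3.21) and the kinase FYN (2.29) were at least 4-fold higher in basophils and 19 differed by less either way. The list median was −0.53, at percentile 0.01 of random lists of like expression. SYK was lower at −2.36, reading 9.45 in basophils, 11.81 in eosinophils and 11.98 in pDC, and LYN read 11.66, 13.02 and 13.20. XBP1, a regulator of secretory capacity, and MANF were 3.89 and 3.41 higher in basophils among 17 genes of secretory machinery. Of 15 immediate early and heat shock genes, 6 were at least 4-fold lower, among them FOS (−4.52) and NR4A2 (−4.10), the last of these dim in basophils.

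Further comparisons set each granulocyte against pDC. Over pDC, the basophils of donor A were higher for TCN1 (9.52), CLC (9.13), HDC (9.13), MS4A3 (8.97), SLC45A3 (8.59) and GATA2 (8.28), and for TRIM51 (7.99), CPA3 (7.84), S100P (7.60) and RHEX (7.26). The eosinophils were higher for CLC (9.01), PRSS33 (7.62), OLIG2 (6.98), PTGDR2 (6.88), FOSB (6.83) and VSTM1 (6.78), and for SIGLEC10 (6.59), S100P (6.57), CD24 (6.57) and ADAM8 (6.31). The pDC exceeded basophils for PTGDS (−8.56), granzyme B (GZMB, −7.86), TNFRSF21 (−7.57), LAMP5 (−7.44) and CCDC50 (−7.43). They also did so for TCL1A (−7.26), JCHAIN (−7.20), LRRC26 (−7.15), the transcription factor SPIB (−6.89) and PACSIN1 (−6.29). Against eosinophils, PTGDS differed by −8.33, GZMB by −8.21, TNFRSF21 by −7.69, CCDC50 by −7.48, JCHAIN by −7.25, TCL1A by −7.23 and LAMP5 by −7.17. NAPSB (−8.40), the interferon regulatory factor IRF8 (−7.66) and TGFBI (−7.25) completed that list. In the cell type with the lower level, 10 of 10 of these genes were dim each way between basophils and pDC, and 6 and 9 of 10 between eosinophils and pDC, so most of these differences are lower bounds too.

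Of 24 pDC identity genes, basophils were at least 4-fold lower for 22 and eosinophils for 21, with medians of −4.85 and −4.94. Basophils were at least 4-fold lower for 8 of 11 MHC class II genes and eosinophils for 5, with HLA-DPA1 at −4.37 and the invariant chain CD74 at −3.23 in basophils. Basophils were at least 4-fold higher for 11 of 13 basophil identity genes (median 5.94), and eosinophils for 8 of 11 eosinophil identity genes (median 5.43). In eicosanoid synthesis, basophils were at least 4-fold higher for ALOX5 (5.13), PTGS1 (2.63), LTC4S (2.27), HPGDS (2.18) and TBXAS1 (2.12). Eosinophils were at least 4-fold higher than pDC for 7 of 15 immediate early and heat shock genes and lower for 7 of 17 genes of secretory machinery, such as HSP90B1 (−3.18) and XBP1 (−3.08). FBL (−2.76), NHP2 (−2.38) and POLR1C (−2.01) were at least 4-fold lower in basophils among 18 ribosome biogenesis genes. SYK and LYN differed by −2.54 and −1.54 between basophils and pDC, and by −0.18 each between eosinophils and pDC. HPGDS, LTC4S and POLR1C were dim in 1 of the 2 cells compared, and CD74 lay near the top of the scale in pDC. The pDC array read 13.84 for MS4A6A and 11.49 for CD14.

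**Figure D4:**
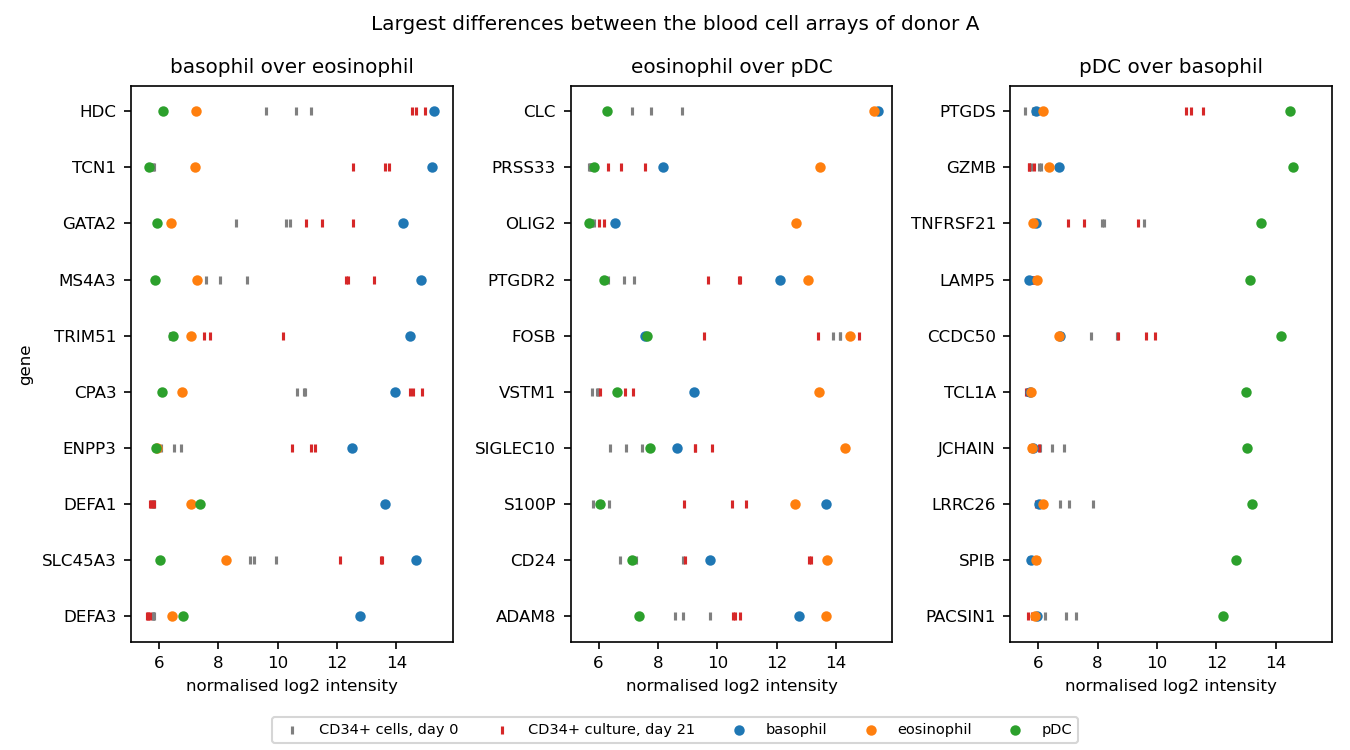
Normalised log2 intensity of the 10 genes with the largest difference for basophils over eosinophils, eosinophils over pDC and pDC over basophils in the 3 arrays of donor A (points), with the 3 day 0 and 3 day 21 CD34 arrays as vertical marks. The first gene of each panel is HDC (8.01), CLC (9.01) and PTGDS (−8.56 as basophils minus pDC).

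In donor A, 262 genes were at least 4-fold higher and 200 lower in basophils than in eosinophils. Against pDC, the counts were 505 and 533 for basophils and 513 and 599 for eosinophils. Between pairs of CD34 arrays of the same day, 59 to 189 genes differed by as much. On the unnamed rows of donors B to E, limma called 4151 of 24526 rows higher and 4249 lower between basophils and eosinophils (n = 4 each, 34.2%). It called 5594 and 5405 rows between basophils and pDC (44.8%), and 6233 and 5492 between eosinophils and pDC (47.8%). With the donor as a block, the counts were 4527 and 4587, 5890 and 5658, and 6533 and 5718. The values as deposited gave 4554 and 1606 rows for basophils and eosinophils and 2803 and 5829 for eosinophils and pDC, and median centring gave 9709 and 5759 for the latter. Across rows, basophils and eosinophils of 1 donor correlated at r = 0.926 ± 0.00367, basophils and pDC at 0.859 ± 0.00846, and eosinophils and pDC at 0.852 ± 0.00384 (SD, n = 5 donors). Basophils were closer to eosinophils than to pDC in 5 of 5 donors (two-sided exact sign-flip p = 0.0625, the smallest possible, 0.0750 adjusted over 6 comparisons).

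The last comparison asks how the blood cell profiles of donor A compare with the culture at day 0 and day 21. Of the 100 genes highest in the basophil array of donor A over both other blood cell types, 40 rose and 3 fell from day 0 to day 21 (53 and 3 adjusted over the list alone). Besides TCN1 and HDC, the receptor gene CD200R1L rose by 5.04, the cyclin CCNA1 by 4.79, RHEX by 3.94 and MAF by 3.76. The set was not of basophil genes alone, since it held 6 neutrophil granule proteins, of which ELANE, CTSG and CEACAM8 rose. Of the 100 eosinophil genes, 17 rose and 4 fell (22 and 7 adjusted over the list alone), with LTC4S at 5.18, SGK1 at 4.62, CXCR4 at 3.48, the ectonucleotidase ENTPD1 at 3.44 and HES4 at −3.83. Of the 6 eosinophil identity genes in that set, 0 rose. Of the 100 pDC genes, 3 rose and 17 fell (9 and 26 adjusted over the list alone). The rising ones were PTGDS at 5.46, LGMN at 4.21 and CYB561A3 at 1.82, and MZB1 (−3.04), SETBP1 (−2.71) and AFF3 (−2.67) were among those that fell.

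Camera placed the basophil set higher (adjusted p = 5.11e-19, and adjusted p = 0.00162 with an estimated correlation) and the eosinophil set higher (0.000136, and adjusted p = 0.00792 with an estimated correlation). It placed the pDC set lower (0.0250), but adjusted p = 0.424 with an estimated correlation, 0.0825 with fry, 0.0505 without the day 0 array of preparation A and 0.359 without its day 21 array. Across genes, the correlation with the basophil array was 0.888 ± 0.00636 at day 21 and 0.821 ± 0.00203 at day 0 (SD, n = 3 each). With eosinophils it was 0.857 ± 0.0103 and 0.804 ± 0.00247, and with pDC 0.842 ± 0.00648 and 0.843 ± 0.00376. Two-sided exact permutation tests gave p = 0.1 for basophils and eosinophils, the smallest that 3 against 3 arrays allow, and 0.9 for pDC (0.15, 0.15 and 0.9 adjusted over 3). Each profile rests on 1 donor, and genes are not independent replicates.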

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

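The measure of bright probes and its groups were chosen after the arrays were seen, and the comparison of probes without a gene name used the planned limma test. Dixon's test was run on 12 sets of 5 values, namely 3 intensity measures in each of the 3 blood cell types and 3 correlations within donors. The pDC array of donor A stood apart in its share of bright probes, at 36.6% against 42.4% to 43.5% in the other 4 donors. Chance gives such a value in about 1 in 20 sets. Its gap to the nearest donor was 0.835 of the range, above the critical value of 0.71. Donor A was also lowest in basophils and eosinophils, with gaps of 0.612 and 0.708, the latter just under that value. The mean intensity of its arrays was the lowest in all 3 cell types too, with gaps of 0.480 to 0.586, so this trait is not particular to its pDC.

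The 2692 probes without a gene name took no part in the comparisons of named genes. Between day 0 and day 21 of the CD34 culture, 94 of these were higher and 88 lower, or 6.76% against 8.21% of the probes with a name. The largest difference was 7.19 on the log2 scale (adjusted p = 0.00424).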

How the results depend on the processing

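The fit of all 21 arrays, the normexp background and the omission of preparation B on both days were tests chosen after the data were seen, and the other alternatives were planned. The cause of a change was not tested except where stated. In the CD34 culture, 756 genes rose and 861 fell, against 301 falling with median centring, 154 and 76 with the values as deposited, and 251 and 226 at adjusted p under 0.01, where fewer pass by construction. Without single arrays the counts ranged from 368 to 674 and from 447 to 684, and without preparation B on both days they were 156 and 127, with fewer arrays by construction. For basophils against day 21, 438 and 433 became 161 and 147 with median centring, 35 and 11 as deposited, 92 and 96 with the compared groups only, 808 and 720 with array weights, and 85 and 73 at adjusted p under 0.01. Without single arrays they ranged from 209 to 382 and from 258 to 352. For eosinophils, 809 and 763 became 520 higher with cyclic loess, 263 and 371 with median centring, 45 and 33 as deposited, 409 and 405 with the compared groups only, 1279 higher with array weights, and 212 and 200 at adjusted p under 0.01. Without single arrays they ranged from 462 to 673 and from 493 to 693. For pDC, 912 and 767 became 394 and 433 with median centring, 121 and 127 as deposited, 491 lower with the compared groups only, and 341 and 236 at adjusted p under 0.01. With all 21 arrays the CD34 counts were 300 and 368, and those against day 21 were 4361 and 3665 for basophils, 4424 and 3657 for eosinophils and 4113 and 3705 for pDC, in a fit that includes the 12 arrays whose values did not follow the probe rows. The row counts of donors B to E moved past 1.5 times under 4 kinds of setting. At least 2-fold differences, which are fewer by construction, were 1059 and 1133 for basophils against eosinophils, 1933 and 2109 for basophils against pDC, and 2114 and 2329 for eosinophils against pDC. The fit of all 21 arrays gave 378 and 355, 876 and 1148, and 1014 and 1283. The values as deposited gave 1606 lower for basophils against eosinophils and 2803 higher for eosinophils against pDC, for which median centring gave 9709 higher. Lists past camera's threshold went from 13 higher and 4 lower to 3 and 2 with an estimated correlation in the CD34 culture, and from 6 and 4 to 0 and 0 for basophils against day 21 (3 and 1 at an unadjusted p under 0.05, 6 and 3 with fry), which became 2 and 7 with all 21 arrays. The basophil and eosinophil lineage sets kept their direction and side of the threshold under all 17 alternatives. The pDC set, at adjusted p = 0.0250, gave 0.424 with an estimated correlation, 0.0825 with fry, 0.0517 without dim genes, 0.287 with all 21 arrays and 0.320 with 50 genes. Without single arrays it ranged from 0.00493 to 0.359. Differences in correlation between day 21 and day 0 were 0.0672 for basophils, 0.0530 for eosinophils and −0.00115 for pDC. Without dim genes the first 2 were 0.0959 and 0.0749, and with Spearman's rho they were 0.0522, 0.0417 and 0.00704. Of the 91 genes of the CD34 culture named by rule, 19 kept their side of the threshold in all 20 settings, 72 lost their call in at least 1 (38 at adjusted p under 0.01, by construction, and 54 with all 21 arrays) and 0 changed direction. Of the 53 of basophils against day 21, 7 kept their side in all 15 settings, 44 lost their call in at least 1 (34 at adjusted p under 0.01 and 13 with all 21 arrays), 2 gained one and 9 changed direction. The gains came with all 21 arrays, in the fit that includes the 12 arrays off the probe rows. The changes of direction came with all 21 arrays too, for IL4 (−1.96), IL5RA (−0.78), INPP5D (−3.14), PTAFR (−0.98), LTB4R (−0.50), C3AR1 (−2.86), CDK1 (1.81), NOP58 (2.76) and MYD88 (−2.79). They came there too for 5 lists, namely basophil identity (adjusted p = 0.0115), mature neutrophil markers (0.648), IgE receptor signalling (0.0460), cytokine receptors (0.0341) and the Toll-like receptor pathway (0.885). Of the 29 lists, 12 stayed on their side of the threshold in all 15 settings of the CD34 culture and 10 in all 10 of the basophil comparison. The counts of genes at least 4-fold apart in donor A stayed within 1.5 times in the 6 settings run. A floor on low values was not run, since no value lay below 1. Signal near the background limits dim genes, and the row counts of donors B to E carry no gene names.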

Other observations

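The tests of another scaling and of alphabetical order, the windows of probes, the correlation between the sets of arrays, the shared interferon level and the list median for macrophage genes were chosen only after the results were seen, and the other tests were planned. In alphabetical order of gene symbols, the values of donors B to E matched those of donor A row by row (r of the levels over 0.7) in 10 of 435 windows of 50 probes. Of these, 5 formed the longest stretch, 250 probes from KPNA2 to LCE1E, which may hold its own names. The adaptor LAT2 was 3.54 higher in their basophils than in their eosinophils (limma, n = 4 each), against 4.92 in donor A, and LAT 3.87 higher, against 3.21. LAMP5, a pDC gene, was −6.90 between basophils and pDC, against −7.44 in donor A, and KYNU −4.34, against −2.74. LAMP3 and LAMP2 were −3.00 and −2.82 between basophils and eosinophils, against −3.36 and −1.96. The stretch was picked for its agreement with donor A, so these values are not independent evidence. Within it, basophil minus pDC differences correlated with donor A at r = 0.928 in place and at most 0.154 at 19 larger offsets. The names could still be wrong, since 45 of 58 windows of probes fitted donor A best at a small offset other than 0. The window from KIF19 to KRTAP19-7, which overlaps the stretch, fitted best at −1, and that from KRTAP20-1 to LIG3 at 0.

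The values of donors B to E did not follow the rows of the 9 other arrays (r = 0.0774 to 0.107). Another scaling keeps ranks and cannot account for a rank correlation of at most 0.109 with donor A, nor can other blood cells, since the highest of these r was 0.107 and the lowest between different cells within the 9 arrays was 0.801. The planned test on genes with more than 1 probe decided nothing, since their basophil minus pDC differences correlated at 0.562 in donor A and 0.153 in donors B to E, between the bounds written for it. Their basophil minus eosinophil differences and mean levels, which had no written bounds, correlated at 0.547 and 0.359 in donor A and 0.207 each in donors B to E. With probes in the alphabetical order of gene symbols, 46 of 58 windows of 300 probes agreed best with donor A at an offset of at most 60 probes (2.9 expected by chance, 0 to 7 in 95%), and for 45 of these that offset was not 0. This is consistent with values displaced by sorting on gene symbols, which stays a hypothesis.

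Of 12 macrophage genes, 5 were higher at day 21 of the CD34 culture (camera adjusted p = 1.35e-05, adjusted p = 0.274 with an estimated correlation). The tables argue against scaling between arrays, since the list median of 2.42 became 2.48 with cyclic loess and 2.55 with median centring. The count of called members fell from 5 to 3 under both, between the bounds written for it, and to 0 with the values as deposited (median 2.68), and why was not tested. Macrophages among the cultured cells may be a source, but the 5 that passed and were higher in all 3 arrays were neither most nor few, and this cannot be told apart from expression in the other cells, since no sort of the culture is labelled. In 7 of the 12 members the day 21 level was highest in preparation B and lowest in A, CD68 and 3 others lay above the median of all values (6.60) at day 0, and LYZ and CSF1R stand in other lists too.

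Of 14 interferon response genes, 12 were brighter in the blood basophils of donor A than at day 21 (camera adjusted p = 7.09e-13, adjusted p = 0.160 with an estimated correlation). The tables argue against scaling here too, with a list median of at least 3.19 under every other scaling run, against 3.35, though the called members fell from 12 to 11 with cyclic loess, 10 with median centring and 5 with the values as deposited. The eosinophils and pDC of the donor lay above day 21 as well, by 4.30 and 2.75, so a level shared by the blood cells of this donor may account for it. Against day 0, the medians were 2.92, 2.58 and 2.20, with 12, 13 and 12 of 14 genes higher. Donor, blood against culture and preparation remain untested, with 1 donor whose values could be named.

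The 6 CD34 arrays allow 10 splits into 3 and 3, too few for a share under 0.05, and 1 of these, the real one, gave as many as 1617 genes, against 0 for the highest other (3945 against 1089 at an unadjusted p under 0.05). The arrays pair by preparation, and among the 4 splits that part all 3 pairs the highest other was also 0 (421 unadjusted). For the rows of donors B to E, 1 of 35 splits, the real one, gave as many rows in each comparison. The counts were 8400 against 1 for basophils and eosinophils, 10999 against 29 for basophils and pDC, and 11725 against 1 for eosinophils and pDC. These splits ignore that the arrays pair by donor, and the 8 of them that part all 4 pairs, as the real one does, are too few for a share under 0.05. Among these 8 the highest other counts were 0, 0 and 1, and the other splits put both arrays of at least 1 donor on the same side.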
